A study of Homo sapiens with 8 samples.

How the data were processed

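RNA from A549 cells, an established human lung adenocarcinoma line, was measured by poly(A)-selected RNA sequencing in 8 libraries. Per the labels' protocols, RNA was purified on spin columns, messenger RNA was isolated with a poly(A) module, and libraries were built with a kit from the same maker as the module. Per the submitters' processing notes, the genome build was hg19 and the tools were STAR and RSEM; their versions and the gene annotation are not given in the sources used here. The authors deposited a gene table per library with 57820 genes, and per the file headers it holds the expected count, the TPM and the FPKM of each gene. Expected counts, per the file headers, are RSEM's estimates, in which a read that fits several genes is divided among them, so they need not be whole. The deposited TPM values are scaled by the authors' pipeline to a fixed total per library and corrected for gene length, and the deposited FPKM values are likewise scaled to length and library size. FPKM values were not used here. Whether the counting used strand is not stated, so values of genes that overlap another gene on either strand, of near-identical copies and of read-through gene models are uncertain. No coordinates are given, since an hg19 annotation was not used here. No spike-in is named in the labels, so all values are relative to the other transcripts of a library.

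The labels put the libraries in 4 groups of 2: empty vector, MGA overexpression vector, siNC (a control siRNA) and siMYC. Each group has a replicate A and a replicate B. Nothing says that these came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The counts of the replicates differed by more than sampling noise in every group, with a chi-square per degree of freedom of 1.18 in the empty vector group, 1.14 in the MGA group, 1.77 in the siNC group and 1.79 in the siMYC group, and all 8 libraries were kept as separate replicates.

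Expected counts were rounded to whole numbers and filtered with filterByExpr (minimum count 10, minimum total 15), which left 11218 genes. Libraries were scaled by TMM and fitted together in edgeR 4.0.16 (R 4.3.3), with 4 groups and 4 residual degrees of freedom, and tested with the quasi-likelihood F test. The common biological coefficient of variation was 0.0623 in this fit. It was 0.0343 in a fit of the overexpression libraries alone and 0.0725 in a fit of the siRNA libraries alone. The joint fit thus shares its dispersions between experiments of unequal spread. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The contrasts were MGA against empty vector, siMYC against siNC, and the difference between these responses (an interaction contrast). The standard error of a log2 fold change was taken as its size divided by the square root of F. Normalised read counts are TMM-scaled counts relative to library size (CPM) and are given as mean ± SD over 2 libraries. All adjusted p-values of single genes come from edgeR unless another tool is named. Gene tests and list tests are two-sided. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333, so none is reported.

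The gene lists (29), the tests, the contrasts, the rule for named genes and the alternatives listed below were fixed before the data were examined. Lists with at least 3 tested members (25) were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera also refers its statistic to the residual degrees of freedom (4), which raises p-values whatever the correlation. With MGA, the lysosome and interferon lists lost their calls at estimated correlations of -0.026 and -0.02, below the preset. A call lost in this setting therefore need not mean that the members of a list move together. Members of a list were also counted with p-values adjusted over the list alone. Genes were named where they belong to the MYC-MAX network list, where they were among the 10 largest rises or 10 largest falls of a comparison (average log2 CPM of at least 1, groups without overlap), where they were among the 4 called members of a list with the smallest p, or where they were among the 5 with the smallest larger p in both comparisons for each joint direction. The report shows a part of the genes this rule gives. For MGA these were picked partly because their calls held in the alternatives, and 31 to 36 calls were lost among the 110 or 111 genes the rule gives for MGA (called or not) when an overexpression library was left out. Other genes are said to have been chosen after their values were seen.

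Overlaps between the comparisons were tested with Fisher's exact test over the genes tested. The comparisons share no libraries. Alternatives were other size factors (RLE, upper quartile, library sizes alone), DESeq2 1.42.0, limma voom, limma-trend on log2(TPM + 1), other filters, a fit of only the 4 libraries of a comparison, a replicate block, other thresholds, and leaving out each library in turn. Counts without the MGA gene were added after the data were seen. A fold against a group with 0 counts was computed against a floor of 3 counts over the group. It takes the counts of the other group as exact, so it is not a lower limit. With 1 to 3 counts in a group the ratio is given with its exact 95% binomial interval. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

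The procedure was tested on simulated data made from the gene means and library sizes, with 200 changed genes. All 8 simulated libraries shared the means of 1 control group, with 1 dispersion per gene. The changed genes were drawn from those above a minimum expected count. In the real data 1005 genes were called with MGA and 4370 with siMYC, and 3742 differed between the control groups. The rates below may therefore not carry over to the real data. With edgeR's dispersions, in the simulated MGA comparison (10640 genes tested), edgeR recovered 25.5% of genes changed 1.5-fold, 53.4% of those changed 2-fold and 88.9% of those changed 4-fold, and 5.6% of its calls were false. In the simulated siMYC comparison (10509 genes tested) it recovered 55.3%, 76.4% and 92.3% at these folds, and 10.5% of its calls were false. With the larger dispersions of DESeq2, edgeR recovered 7.7%, 35.6% and 74.2% in the simulated MGA comparison, with 9.4% of its calls false, and 12.5%, 29.9% and 79.1% in the simulated siMYC comparison, with 6.7% false. Library totals ran from 820428 to 2129006 expected counts, so small changes of weakly expressed genes were often beyond reach.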

Results

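The study measured the transcriptome of A549 lung adenocarcinoma cells in a pair of experiments. In one, cells carried an empty vector or a vector that overexpresses MGA, a DNA-binding protein that pairs with MAX, the partner of the MYC oncoprotein. In the other, cells were treated with a control siRNA (siNC) or with an siRNA against MYC (siMYC). Each of the 4 groups had 2 libraries. Total expected counts were 844477 and 820428 in the empty vector libraries, 1176890 and 917548 in the MGA libraries, 1398805 and 1741730 in the siNC libraries, and 2129006 and 1598792 in the siMYC libraries. The title of the series names repression of MYC target genes by MGA as its subject. The comparisons therefore ask which genes respond to MGA, which respond to loss of MYC, and how far these responses share genes.

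The manipulated genes were examined first. MGA (ENSG00000174197.12) stood at 102500 and 103700 CPM in the MGA libraries and at 121.6 and 81.54 CPM in the empty vector libraries. Its log2 fold change was 9.98 (SE 0.10, adjusted p = 1.2e-32), and its reads made up 9.54% and 9.68% of all counts in the MGA libraries. MYC (ENSG00000136997.10) fell with siMYC from 201 ± 26 to 44.7 ± 5.05 CPM (SD, n = 2), a log2 fold change of -2.15 (SE 0.14, adjusted p = 2.9e-12 in edgeR). MGA did not differ detectably in CPM between siMYC (47.5 ± 2.99 CPM) and siNC (48.4 ± 0.79 CPM), with a log2 fold change of -0.02 (SE 0.13). In the deposited TPM, which corrects for length, MGA was higher with siMYC (8.165 ± 0.375) than with siNC (5.975 ± 0.0636). The cause of this disagreement was not tested. MYC was higher with MGA, at 321 ± 36.3 against 237 ± 5.07 CPM (log2 fold change 0.43, SE 0.12, adjusted p = 0.025 in edgeR). This last call is weak: it was lost with upper-quartile size factors, with library sizes alone, with DESeq2, on TPM, and without 3 of the 4 libraries in turn. The log2 fold change was 0.41 without empty vector replicate A (adjusted p = 0.17), 0.45 without empty vector replicate B (adjusted p = 0.14) and 0.32 without MGA replicate B (adjusted p = 0.27).

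**Figure D1:**
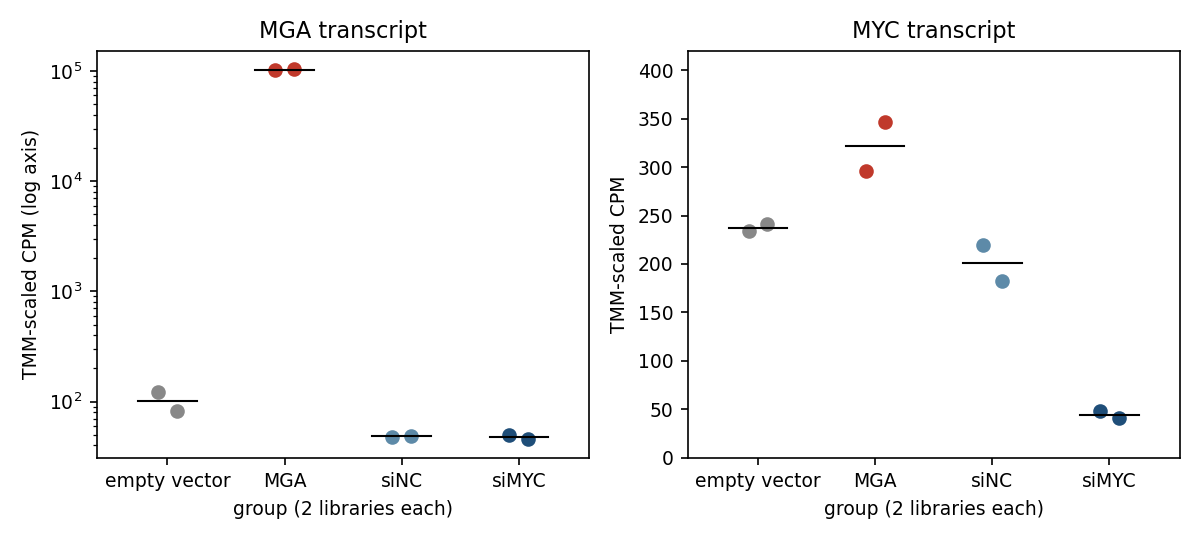
TMM-scaled CPM of MGA (left, log axis) and MYC (right, linear axis from 0) in the 8 libraries; points are libraries and bars are group means. MGA lies at 102500 and 103700 CPM in the 2 MGA libraries, and MYC is lowest in the siMYC libraries, at 48.26 and 41.12 CPM.

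With MGA overexpression, 17 of 35 tested mitosis genes fell, and that list was lower than other genes also with an estimated correlation (adjusted p = 0.01). Of the DNA replication list 13 of 39 genes fell, of nucleotide synthesis 9 of 25, of glycolysis 7 of 16, of MYC targets 11 of 55 and of mitochondrially encoded genes 10 of 13, and 10 of 24 p53 targets rose. These list calls were lost with an estimated correlation (adjusted p = 0.22 for DNA replication, adjusted p = 0.12 for p53 targets and adjusted p = 0.15 for each of the others). The mitochondrial chaperonin pair HSPD1 and HSPE1, both MYC targets, fell: HSPD1 went from 1120 ± 7.09 to 520 ± 12.3 CPM (SD, n = 2; log2 fold change -1.11, SE 0.09, adjusted p = 1.5e-09 in edgeR). TOP2A, the topoisomerase of dividing cells, fell from 496 ± 21.5 to 261 ± 23.7 CPM. GADD45A, a DNA damage response gene, rose from 371 ± 31.7 to 803 ± 25.5 CPM (log2 fold change 1.12, SE 0.11, adjusted p = 7.1e-08). Of 11218 genes tested, 1005 changed, 556 upward and 449 downward, and 139 and 99 of these changed 2-fold or more.

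The split between rises and falls moved with the scaling: it was 387 to 628 with upper-quartile size factors and 300 to 821 with library sizes alone, which moved the median of all genes to a log2 fold change of -0.116. Groups did not overlap in 52.6% of genes, against 33.3% by chance. The count rests on both libraries of each group: it was 402 without MGA replicate A, 474 without MGA replicate B, 434 without empty vector replicate A and 405 without empty vector replicate B. DESeq2 called 279 genes and limma-trend on TPM called 82. A fit of only the 4 overexpression libraries, with 2 residual degrees of freedom, called 1381 of 9660 genes.

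Of 55 tested MYC targets, 11 fell, 1 rose and 43 did not pass, and 13 fell and 1 rose when adjusted over the list alone. The median log2 fold change was -0.20, and the list was lower than other genes (camera adjusted p = 5.1e-06; adjusted p = 0.15 with an estimated correlation). HSPE1 fell by 1.46 on the log2 scale, and NPM1, a nucleolar protein, fell by 0.51. Genes of ribosome production moved little: 3 of 41 ribosome biogenesis genes fell, among them NCL (log2 fold change -0.81, SE 0.08), with a list median of -0.12 (camera adjusted p = 0.034; adjusted p = 0.24 with an estimated correlation) and the same 3 adjusted over the list alone. Of 76 cytosolic ribosomal proteins, 4 fell, including RPL10, also 4 adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.0095; adjusted p = 0.53 with an estimated correlation). Of 21 translation factors, 2 fell (3 adjusted over the list alone; camera adjusted p = 0.048; adjusted p = 0.33 with an estimated correlation). The ribosome biogenesis call was lost without MGA replicate A, with DESeq2 and on TPM, and the ribosomal protein call with fry and with DESeq2. The translation factor call was lost with RLE size factors, with DESeq2, on TPM and without each of the 4 libraries in turn.

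In the mitosis list, 17 of 35 genes fell and 0 rose, 23 adjusted over the list alone, with a median log2 fold change of -0.74 (camera adjusted p = 4.8e-15; adjusted p = 0.01 with an estimated correlation). HMMR fell by 1.33, TOP2A by 0.93, CCNB1 (cyclin B1) by 0.86 and MKI67 (the Ki-67 antigen) by 0.71 on the log2 scale. In the DNA replication list, 13 of 39 genes fell and 0 rose, 21 adjusted over the list alone, with a median of -0.67 (camera adjusted p = 1.5e-11; adjusted p = 0.22 with an estimated correlation); FEN1 fell by 0.99 and PCNA, the polymerase clamp, by 0.68. Of 25 genes of nucleotide and one-carbon synthesis, 9 fell, 14 adjusted over the list alone, with a median of -0.51 (camera adjusted p = 1.6e-09; adjusted p = 0.15 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 1.07, CAD by 0.98 and PAICS by 0.77.

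Of 16 glycolysis genes, 7 fell, 8 adjusted over the list alone, with a median of -0.33 (camera adjusted p = 1.5e-09; adjusted p = 0.15 with an estimated correlation). LDHA (lactate dehydrogenase) fell from 1370 ± 52.7 to 758 ± 25.3 CPM, the lactate exporter SLC16A3 by 0.89 and ENO1 (enolase) by 0.79 on the log2 scale. Of 51 nuclear genes of oxidative phosphorylation, 1 fell, also 1 adjusted over the list alone, and the list median was -0.07. Of 13 protein-coding genes of the mitochondrial genome, 10 fell, 12 adjusted over the list alone, with a median of -0.46 (camera adjusted p = 3.1e-16; adjusted p = 0.15 with an estimated correlation). MT-CO2 fell from 3420 ± 23.3 to 2200 ± 27.3 CPM. Mitochondrial reads made up 2.73% and 2.74% of counts in the MGA libraries and 3.97% and 3.86% in the empty vector libraries.

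The p53 target list moved the other way: 10 of 24 genes rose and 0 fell, 15 adjusted over the list alone, with a median log2 fold change of 0.59 (camera adjusted p = 1.5e-12; adjusted p = 0.12 with an estimated correlation). MDM2, the p53 ubiquitin ligase, rose from 310 ± 6.44 to 560 ± 22.1 CPM, XPC rose by a log2 fold change of 0.87 and AEN by 0.60. Of 20 NF-kB and inflammatory genes, 5 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0016; adjusted p = 0.65 with an estimated correlation), with TNFAIP3 and NFKB2 higher by 0.81 and 0.71 and the cytokine gene LIF lower. Of 24 NRF2 targets, 7 fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.69 with an estimated correlation). The aldo-keto reductases AKR1C1, AKR1C2 and AKR1C3, close copies that can share reads, had log2 fold changes of -0.91, -0.63 and -0.73, and HMOX1, heme oxygenase, rose by 1.17. The NF-kB list call was lost with fry, with DESeq2 and on TPM, the NRF2 list call with fry, and the LIF call without empty vector replicate A, without MGA replicate B, with DESeq2 and on TPM. On TPM the calls of TNFAIP3 and NFKB2 were lost as well.

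Of 30 interferon response genes, 6 fell and 1 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.031; adjusted p = 0.15 with an estimated correlation), with BST2 and OAS3 lower (log2 fold changes -1.28 and -0.44). This list call was lost without MGA replicate A, with DESeq2 and on TPM, where the calls of BST2 and OAS3 were lost too. Of 27 lysosome genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.024; adjusted p = 0.15 with an estimated correlation). SQSTM1, an autophagy receptor, rose by a log2 fold change of 0.63. The lysosome list call was lost with upper-quartile size factors, with library sizes alone, with DESeq2 and without empty vector replicate B. The remaining lists, the MYC-MAX network list aside, did not differ from other genes by camera, apart from the lung and epithelial list without empty vector replicate A and without MGA replicate B. Among tRNA synthetases 3 of 18 rose and 1 fell (4 and 1 adjusted over the list alone), in the integrated stress response 3 of 20 rose and 1 fell (4 and 2 adjusted over the list alone), and in the unfolded protein response 2 of 15 rose and 4 fell (2 and 6 adjusted over the list alone). Among TGF-beta, matrix and mesenchymal genes 4 of 27 rose and 3 fell (4 and 4 adjusted over the list alone), and among lung and epithelial genes 1 of 17 rose and 1 fell (1 and 2 adjusted over the list alone). In the PRC1.6 complex, to which MGA belongs, 2 of 13 genes fell (2 adjusted over the list alone), and 1 of 24 cholesterol synthesis genes rose (0 adjusted over the list alone). In the hypoxia list 1 of 15 fell (1 adjusted over the list alone), and of 37 germline and meiosis genes 4 could be tested and 0 changed, also 0 adjusted over the list alone. In the stress response list, DDIT3 (CHOP) rose by 1.17 and the amino acid transporter SLC7A5 fell by 0.84.

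In the MYC-MAX network list, MGA, MYC and MNT, a repressor that also pairs with MAX, rose with MGA (3 of 10 tested; 5 adjusted over the list alone; camera adjusted p = 2e-32). That test is carried by MGA itself: without MGA and MYC, an alternative chosen after the values were seen, 1 of 8 genes rose (3 adjusted over the list alone) and camera did not separate them from other genes. MNT had a log2 fold change of 0.99 (SE 0.27, adjusted p = 0.019 in edgeR), and its call was lost without empty vector replicate A, without empty vector replicate B and without MGA replicate B.

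The genes with the largest fitted changes in the MGA comparison were mostly weakly expressed. The sodium-proton exchanger SLC9A2 had 0 counts in the MGA libraries and 6 and 5 in the empty vector libraries. Against the floor of 3 counts it was 4.22-fold lower, a value without an interval. LRRC45 fell by 2.47 on the log2 scale (SE 0.47, adjusted p = 0.00087). The virus receptor gene CXADR was higher by a ratio of 8.12 (95% interval 2.51 to 41.7) and the keratin gene KRT14 by a ratio of 7.54 (2.31 to 38.9). GOLGA6L9, FAM156A, SPCS2P4 and AGAP9 also ranked here, but each has a near-identical copy, so their values are uncertain: with the copies summed, log2 fold changes were 0.36, -0.56, -0.35 and 0.83.

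Knockdown of MYC lowered 39 of 41 tested ribosome biogenesis genes, 20 of 21 translation factors, 23 of 25 nucleotide synthesis genes, 35 of 39 DNA replication genes and 29 of 35 mitosis genes, and it raised 20 of 27 matrix and 20 of 27 lysosome genes. With an estimated correlation the list calls of nucleotide synthesis (adjusted p = 0.058), DNA replication (adjusted p = 0.17) and matrix genes (adjusted p = 0.088) were lost. The correlation was estimated at -0.004 for the mitosis list, which kept its call, and at 0.38 for DNA replication. The fewer degrees of freedom of this setting applied to every list. NPM1 fell from 2010 ± 14 to 655 ± 5.28 CPM (SD, n = 2; log2 fold change -1.62, SE 0.07, adjusted p = 6.8e-15 in edgeR). TRAP1, a mitochondrial chaperone, fell from 212 ± 4.02 to 32.2 ± 3.87 CPM (log2 fold change -2.70, SE 0.14). Of 11218 genes tested, 4370 changed, 2130 upward and 2240 downward, and 574 and 576 of these changed 2-fold or more. The split moved with the scaling: it was 2399 to 2057 with RLE size factors, 2379 to 2063 with upper-quartile size factors, 2384 to 2066 with library sizes alone and 2537 to 1974 without the MGA gene in the counts. Groups did not overlap in 67.6% of genes, against 33.3% by chance. DESeq2 called 1562 genes and limma-trend on TPM called 1245. A fit of only the 4 siRNA libraries called 4135 of 11045 genes.

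Of 55 tested MYC targets, 53 fell and 0 rose, 54 adjusted over the list alone, with a median log2 fold change of -1.23 (camera adjusted p = 1.1e-42; adjusted p = 0.026 with an estimated correlation). NOP56, NOLC1 and HSPD1 had log2 fold changes of -1.78, -1.69 and -1.53. Of 41 ribosome biogenesis genes, 39 fell, 39 also adjusted over the list alone, with a median of -1.10 (camera adjusted p = 1.6e-31; adjusted p = 0.026 with an estimated correlation), among them DDX21 and DKC1 (log2 fold changes -1.75 and -1.67). Of 76 cytosolic ribosomal proteins, 75 fell, 76 adjusted over the list alone, with a median of -0.66 (camera adjusted p = 3.2e-38; adjusted p = 0.028 with an estimated correlation); RPS2 fell by 1.10 and RPS3 by 1.01. Of 21 translation factors, 20 fell, 20 also adjusted over the list alone (camera adjusted p = 2.4e-15; adjusted p = 0.028 with an estimated correlation), with EIF5A lower (log2 fold change -1.12). Of 18 tRNA synthetases, 13 fell, 13 also adjusted over the list alone (camera adjusted p = 2.8e-07; adjusted p = 0.079 with an estimated correlation).

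Of 25 nucleotide and one-carbon synthesis genes, 23 fell, 24 adjusted over the list alone, with a median of -1.17 (camera adjusted p = 2.4e-25; adjusted p = 0.058 with an estimated correlation). PAICS, of purine synthesis, fell from 348 ± 1.58 to 86.6 ± 19.1 CPM. Of 39 DNA replication genes, 35 fell, 36 adjusted over the list alone, with a median of -0.97 (camera adjusted p = 8e-16; adjusted p = 0.17 with an estimated correlation), led by DTL (log2 fold change -2.27, SE 0.19). Of 35 mitosis genes, 29 fell, 29 also adjusted over the list alone, with a median of -0.58 (camera adjusted p = 3e-10; adjusted p = 0.026 with an estimated correlation); AURKB fell by 1.13, CDC20 by 1.12 and CDK1 by 1.07. Of 51 oxidative phosphorylation genes, 25 fell and 0 rose, 26 adjusted over the list alone (camera adjusted p = 8.2e-06; adjusted p = 0.2 with an estimated correlation), with CYC1 and CYCS, both cytochromes, lower (log2 fold changes -1.21 and -1.20). Of 16 glycolysis genes, 10 fell and 3 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.00044; adjusted p = 0.29 with an estimated correlation), with GPI lower (log2 fold change -0.99). Of 13 mitochondrially encoded genes, 2 fell (1 adjusted over the list alone), with a median of -0.08.

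Of 27 TGF-beta, matrix and mesenchymal genes, 20 rose with siMYC and 1 fell, the same numbers adjusted over the list alone, with a median of 0.75 (camera adjusted p = 3e-12; adjusted p = 0.088 with an estimated correlation). TGFB2 rose by a log2 fold change of 1.47 and FN1, fibronectin, by 1.30. The fibroblast collagen COL1A1, the 1 tested member of the fibroblast marker list, rose by 2.23 (SE 0.17), and the 1 tested leukocyte marker, CD68, by 0.86 (SE 0.21); with MGA their log2 fold changes were 0.20 and -0.31. No member of the endothelial list or of the list of 19 replication-dependent histone genes was abundant enough to be tested. Of 27 lysosome genes, 20 rose and 1 fell, 22 and 1 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 4e-07; adjusted p = 0.026 with an estimated correlation). GABARAPL1, of autophagosomes, rose by 2.20 and the protease gene CTSD by 0.91, and NPC1 fell by 1.22.

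Of 24 NRF2 targets, 13 rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 0.00087; adjusted p = 0.54 with an estimated correlation), with the drug exporter ABCC3 higher by a log2 fold change of 1.13. Of 15 unfolded protein response genes, 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00048; adjusted p = 0.29 with an estimated correlation), with PDIA4 higher by 1.20 and DNAJC3 by 1.24. Of 17 lung and epithelial genes, 7 rose and 3 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.02; adjusted p = 0.48 with an estimated correlation), with KRT19 higher by 1.23. The lung list call was lost with fry, DESeq2 and voom, and without siNC replicate A and without siMYC replicate B, where its median was 0.46 and 0.26. The NRF2 list call was lost with fry and without siMYC replicate B, at 0.15.

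The other lists did not differ from other genes by camera with siMYC. Of 24 p53 targets 5 rose and 2 fell, also adjusted over the list alone, with CDKN1A (p21) higher by 1.16 and AEN lower (log2 fold change -0.92). Of 20 stress response genes 6 rose and 9 fell (6 and 10 adjusted over the list alone), and PSAT1 of serine synthesis fell by 1.32. Cholesterol synthesis had 8 rises and 1 fall among 24 (9 and 1 adjusted over the list alone), led by INSIG1 at 1.38. Hypoxia genes were split, with 5 rises and 4 falls among 15 (6 and 4 adjusted over the list alone): VEGFA rose by 0.91, and the carbonic anhydrase CA9 fell by 2.97. Of 30 interferon genes 2 rose and 1 fell, also adjusted over the list alone, but 14 of the 30 had under 10 counts in each siRNA library, so the test says little about this list. In the NF-kB list 2 of 20 rose and 3 fell (2 and 2 adjusted over the list alone), with PTGS2 higher by 1.13; its direction by camera was upward while its median was -0.13, and 4 of the 20 had under 10 counts in each siRNA library. That list turned with single libraries: its median was 0.70 without siNC replicate A (adjusted p = 0.014) and -0.78 without siNC replicate B (adjusted p = 0.0052). In the PRC1.6 complex 1 of 13 rose and 5 fell, also adjusted over the list alone, and 0 of 4 germline genes changed, also 0 adjusted over the list alone.

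In the MYC-MAX network list, 3 of 10 genes rose and 2 fell with siMYC, also adjusted over the list alone. MXD4, a MAX-binding repressor, rose by a log2 fold change of 1.66 (SE 0.18, adjusted p = 3.9e-08 in edgeR), MLXIP by 0.73 and MNT by 0.51; MLX fell by 0.55. MAX had a log2 fold change of -0.18 (SE 0.19). The calls of MNT and MLX were lost without siNC replicate A, among other left-out libraries.

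Among the largest changes with siMYC, BMF, a pro-apoptotic gene, rose by a log2 fold change of 4.41 (SE 0.43, adjusted p = 5.1e-09), POLR3G, a subunit of RNA polymerase III, fell by 2.50 (SE 0.27) and MZT1, of the microtubule organiser, by 2.44 (SE 0.31). The hexokinase gene HK2 was lower by a ratio of 0.0744 (95% interval 0.00173 to 0.512), and SPOCD1 was higher by a ratio of 18 (4.7 to 153). VPS9D1-AS1, an antisense gene, fell by 3.61. Its value is uncertain because the use of strand is not stated, and counting without strand could mix its reads with those of its partner. DYX1C1-CCPG1, TRIM34 and HIST2H2AA3 ranked among the largest rises, but each shares reads with a copy or a read-through model. With these summed, the log2 fold changes were 0.68, 1.57 and 1.24.

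**Figure D2:**
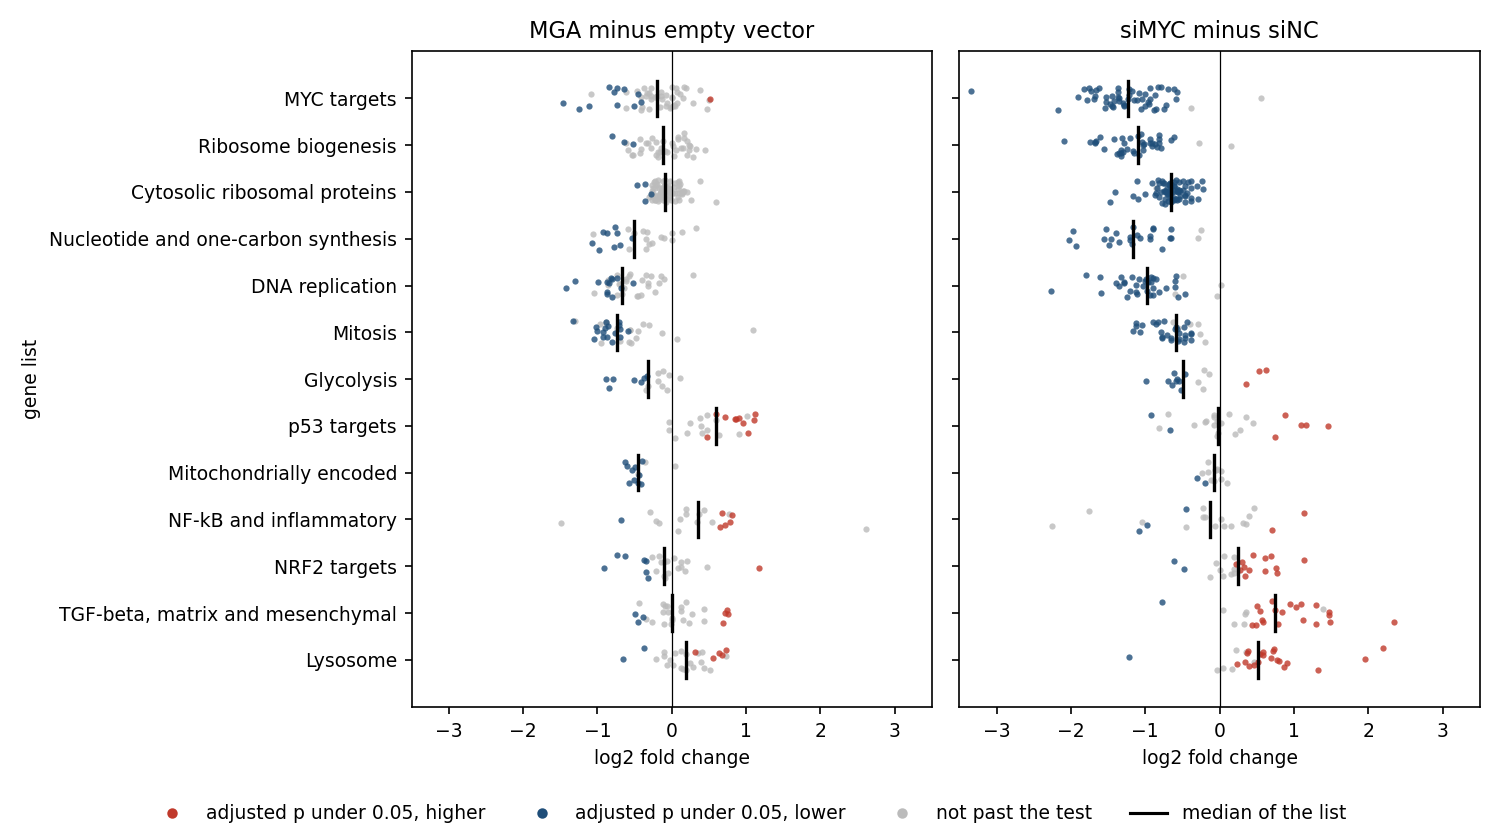
Log2 fold changes of the tested members of 13 gene lists with MGA (left) and with siMYC (right); each point is a gene, coloured where the edgeR adjusted p is under 0.05, and black bars are list medians. With siMYC, 53 of 55 MYC targets fell and 75 of 76 cytosolic ribosomal proteins fell; with MGA, 11 and 4 fell, while 17 of 35 mitosis genes fell and 10 of 24 p53 targets rose.

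The responses to MGA and to loss of MYC shared part of their falling genes. HSPD1, HSPE1, NCL, HSP90AB1 and the RNA-binding protein HNRNPA1 fell in both, and JUNB, ABCA1, NAV2 and TNFAIP2 rose in both. Of the 449 genes lower with MGA, 214 were also lower with siMYC, against 89.7 for independent lists (odds ratio 3.93, 95% interval 3.23 to 4.78, Fisher's exact adjusted p = 6.8e-41). For genes higher in both the overlap was 177 against 105.6 (odds ratio 2.08, 95% interval 1.72 to 2.51, adjusted p = 2.6e-13). In all, 391 of 535 genes called in both had the same direction. That number was 173 without empty vector replicate A, 166 without empty vector replicate B, 154 without MGA replicate A and 196 without MGA replicate B, 102 with DESeq2 and 23 with limma-trend on TPM. The totals called in both are not given for these settings, so the numbers do not show whether the share in agreement changed. Genes are not independent of one another, so the overlap p-values describe gene lists and not samples.

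As a set, the 2240 genes lower with siMYC were lower with MGA, with a median log2 fold change of -0.131 against 0.054 for other genes (camera p = 7.3e-07; p = 0.0083 with an estimated correlation). This set comes from the siRNA libraries, which do not enter the MGA contrast. The 2130 genes higher with siMYC had a median of 0.071 with MGA, and camera did not separate them from other genes (p = 0.066; p = 0.054 with an estimated correlation). They passed that test without siMYC replicate B and without the MGA gene in the counts, an alternative added later. With library sizes alone, which moved the median of all genes to -0.116, their median was -0.053. Across all genes the log2 fold changes correlated weakly (Pearson's r = 0.113, Spearman's rho = 0.163), a correlation across genes within these libraries; r was 0.045 without MGA replicate A, 0.044 without siMYC replicate A, 0.026 with no filter on low counts, 0.048 with a filter of CPM of at least 1 in 2 libraries, 0.199 with DESeq2 and 0.188 with the 4 libraries of a comparison (each a correlation of log2 fold changes across genes).

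The responses differed for 2076 genes by the interaction contrast (663 with DESeq2, 347 with limma-trend on TPM, 1309 without MGA replicate A, 1373 without empty vector replicate B). MYC targets fell less with MGA: 39 of 55 differed in that direction, with a median difference of 1.11 (camera adjusted p = 1.8e-23; adjusted p = 0.049 with an estimated correlation). The same held for 61 of 76 cytosolic ribosomal proteins (adjusted p = 2.2e-28; adjusted p = 0.049 with an estimated correlation) and 31 of 41 ribosome biogenesis genes (adjusted p = 7.4e-23; adjusted p = 0.036 with an estimated correlation) and 12 of 21 translation factors (adjusted p = 3.8e-10; adjusted p = 0.049 with an estimated correlation). The control groups were compared too, a comparison chosen after the data were seen, in which called members were counted and no list test was run. Of all 11218 genes tested, 2015 were lower and 1727 higher with the empty vector than with siNC. Lower were 23 of 55 MYC targets, 37 of 76 ribosomal proteins, 11 of 41 ribosome biogenesis genes and 9 of 21 translation factors, and 0, 2, 2 and 0 were higher. The other lists named in this paragraph were counted likewise: nucleotide synthesis (17 of 25 lower, 0 higher), tRNA synthetases (3 of 18 lower, 5 higher), oxidative phosphorylation (26 of 51 lower, 0 higher), DNA replication (16 of 39 lower, 0 higher), mitosis (29 of 35 lower, 0 higher) and glycolysis (7 of 16 lower, 2 higher). Counts were also made for p53 targets (2 of 24 lower, 13 higher), mitochondrially encoded genes (2 of 13 lower, 7 higher), matrix genes (6 of 27 lower, 10 higher) and NRF2 targets (16 of 24 lower, 3 higher). The last counts were for the unfolded protein response (1 of 15 lower, 4 higher), lysosome genes (0 of 27 lower, 12 higher), lung and epithelial genes (6 of 17 lower, 3 higher) and the MYC-MAX network (1 of 10 lower, 2 higher). In ribosome biogenesis, the unfolded protein response and the MYC-MAX network the share that differed was near that of all genes. Of 25 nucleotide synthesis genes 12 differed upward and 1 downward (adjusted p = 6.6e-08; adjusted p = 0.22 with an estimated correlation), of 18 tRNA synthetases 11 upward (adjusted p = 4.2e-08; adjusted p = 0.13 with an estimated correlation), and of 51 oxidative phosphorylation genes 5 upward (adjusted p = 0.0017; adjusted p = 0.31 with an estimated correlation). Of 39 DNA replication genes 7 differed upward and 0 downward (adjusted p = 0.027; adjusted p = 0.56 with an estimated correlation). The mitosis list as a whole did not pass the test (median difference -0.13, adjusted p = 0.47), with 1 of 35 genes differing upward and 2 downward. Nor did the glycolysis list (adjusted p = 0.88), whose genes went both ways, with 4 of 16 differing upward and 4 downward. The p53 list had a higher log2 fold change with MGA than with siMYC, with 9 of 24 genes differing upward and 2 downward (adjusted p = 0.0039; adjusted p = 0.31 with an estimated correlation). Mitochondrially encoded genes had lower log2 fold changes with MGA than with siMYC, 7 of 13 differing (adjusted p = 2.4e-05; adjusted p = 0.31 with an estimated correlation). TGF-beta and matrix genes also had lower log2 fold changes with MGA than with siMYC, 11 of 27 differing downward and 1 upward (adjusted p = 1.1e-08; adjusted p = 0.14 with an estimated correlation). The log2 fold changes differed in the same direction for NRF2 targets, 12 of 24 downward and 2 upward (adjusted p = 2.9e-07; adjusted p = 0.33 with an estimated correlation), and for the unfolded protein response, 9 of 15 downward and 1 upward (adjusted p = 1.7e-05; adjusted p = 0.23 with an estimated correlation). They did so too for lysosome genes, which had medians of 0.19 with MGA and 0.52 with siMYC, 9 of 27 downward and 2 upward (adjusted p = 0.0013; adjusted p = 0.077 with an estimated correlation), and for lung and epithelial genes, 5 of 17 downward (adjusted p = 0.0032; adjusted p = 0.33 with an estimated correlation). The difference in the MYC-MAX network list (adjusted p = 2.5e-09) was carried by MGA and MYC, without which it did not pass (adjusted p = 0.85).

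Some genes moved in opposite directions. The tight-junction gene CLDN2 fell with MGA from 147 ± 45.3 to 47.8 ± 1.79 CPM and rose with siMYC from 115 ± 12.1 to 321 ± 41 CPM. CYP24A1, which breaks down vitamin D, had log2 fold changes of -1.10 and 0.94, AKR1C3 of -0.73 and 0.77, and IGFBP4 of -0.63 and 0.55. FOSL1, an AP-1 subunit, had 0.88 with MGA and -1.19 with siMYC. Genes higher with MGA and lower with siMYC numbered 49, below the 111 of independent lists (odds ratio 0.374, 95% interval 0.272 to 0.504), and genes lower with MGA and higher with siMYC numbered 95, against 85.3 (odds ratio 1.15, 0.904 to 1.46, adjusted p = 0.24).

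**Figure D3:**
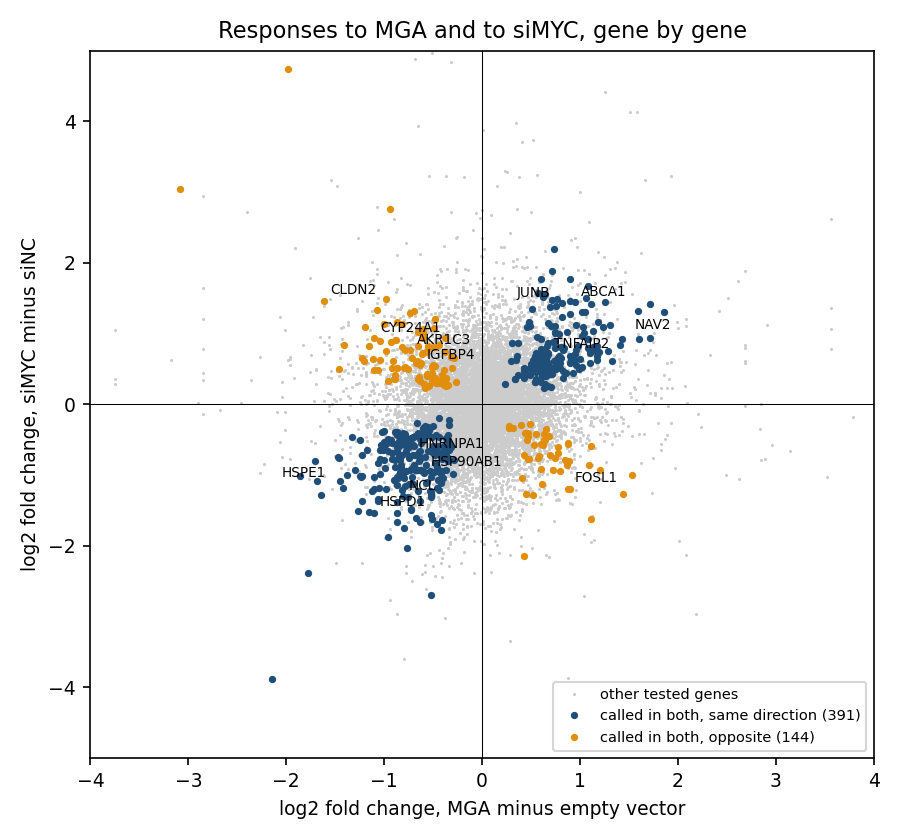
Log2 fold change with siMYC (vertical axis) against log2 fold change with MGA (horizontal axis) for the tested genes; coloured points are genes called in both comparisons, and 24 genes beyond the axes are not drawn, 1 of them called in both. The 391 genes called in the same direction outnumber the 144 called in opposite directions.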

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

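Counts without the MGA gene were an alternative chosen after the data were seen; the others were planned. The MYC targets list, MGA vs empty vector, had medians of -0.324 to -0.18 and stayed past the threshold, except with an estimated correlation (-0.195, adjusted p = 0.15). The genes lower with siMYC, in MGA vs empty vector, stayed past it in the alternatives run, at -0.264 to -0.121. For genes changed, MGA vs empty vector, stricter thresholds left 238 (2-fold) and 447 (adjusted p under 0.01), and 1150 changed 2-fold with siMYC. DESeq2 called 279 with MGA (118 higher, 161 lower) and 1562 with siMYC (723 higher, 839 lower), and 663 differed between responses. All 279 and 1561 of the 1562 were called by edgeR too. DESeq2 tested fewer genes (4724 and 8804) at a larger median biological coefficient of variation (0.201 against 0.065 in edgeR). With limma-trend on log2(TPM + 1), 82 changed with MGA (32 higher, 50 lower), 1245 with siMYC (709 higher, 536 lower), and 347 differed; the cause was not tested. With library sizes alone, 300 were higher and 821 lower with MGA, as the median of all genes moved to -0.116. The correlation of log2 fold changes across genes was 0.199 with DESeq2, 0.026 with no filter, 0.048 with a filter of CPM of at least 1 in 2 libraries, and 0.188 with the 4 libraries of a comparison; the cause was not tested. Genes called in both in the same direction numbered 102 with DESeq2 and 23 with TPM.

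The MYC transcript, MGA vs empty vector, was not called with upper-quartile size factors (0.354, adjusted p = 0.069), library sizes alone (0.301, adjusted p = 0.12), DESeq2 (0.433, adjusted p = 0.19) or TPM (0.435, adjusted p = 0.2); the cause was not tested. The genes higher with siMYC, in MGA vs empty vector, passed the test with fry (0.071), which does not compare them with other genes, and without the MGA gene (0.06); the cause was not tested.

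Leaving out a library assumes that its lone partner varies like the other groups. Without an overexpression library, 402 to 474 genes changed with MGA (196 to 267 higher, 192 to 220 lower), with fewer samples; without an siRNA library, 1072 to 1121 did. Without an overexpression library the MYC transcript, MGA vs empty vector, ranged from 0.316 to 0.548. Leaving out any 1 of the 8 libraries, genes whose responses differ ranged from 1309 to 1937, the correlation of log2 fold changes across genes from 0.044 to 0.13, and the genes higher with siMYC, in MGA vs empty vector, from 0.055 to 0.092. The overlap of genes called in both comparisons, same direction, ranged from 154 to 433. The NF-kB and inflammatory list, siMYC vs siNC, went from -0.833 to 0.703 and was called downward without siNC replicate B (-0.784); the cause was not tested.

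The labels do not say that equal replicate letters mark a shared day; deviations of A from B correlated at -0.021 between the overexpression groups and 0.133 between the siRNA groups. With a replicate block, 1176 genes changed with MGA, 4657 with siMYC, and 2292 differed. Of 813 values of other lists, 749 kept direction and side of the threshold, 51 lost the call, 12 gained one and 1 reversed. Of 3503 values of named genes, 3175 kept both, 326 lost the call (101 of them on TPM), 2 gained one and 0 reversed. Totals of 820428 to 2129006 counts limit weakly expressed genes.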

Other observations

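The tests of the mitochondrial share and of summed gene models were chosen after the values they rest on were seen, as were the comparison of the control groups and the genes named in it. The control groups of the experiments differed widely in interferon genes, which belongs to no comparison of the design. All 30 interferon response genes were higher in the empty vector libraries than in the siNC libraries in the same edgeR fit, as were 18 of 20 NF-kB and inflammatory genes. IFIT1 stood at 1180 ± 47.4 CPM (SD, n = 2) with the empty vector and 1020 ± 38.5 CPM with MGA, against 2.4 ± 2.38 CPM with siNC and 1.3 ± 0.107 CPM with siMYC. OAS3 stood at 1370 ± 34.9 and 1010 ± 0.13 CPM against 116 ± 1.2 and 84.4 ± 2.19 CPM. Of the p53 targets, 13 of 24 were higher and 2 lower with the empty vector than with siNC, and of the mitosis list 29 of 35 were lower. MYC targets were lower in 23 of 55, cytosolic ribosomal proteins in 37 of 76 and nucleotide synthesis genes in 17 of 25. Experiment and vector cannot be separated here. Of the 11218 genes tested, 3742 differed between these control groups, 1727 higher and 2015 lower with the empty vector.

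Background MGA levels differed as well. The empty vector libraries held 105 and 68 MGA counts (101.6 ± 28.3 CPM) and the siNC libraries 67 and 84 (48.42 ± 0.792 CPM).

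Mitochondrial messenger RNAs fell with MGA, with a median log2 fold change of -0.46 over 13 genes. A loss of share to MGA reads is argued against, because with MGA counts left out the mitochondrial share still fell to 3.02% and 3.03% from 3.97% and 3.86%, a log2 ratio of -0.37. A general fall of abundant transcripts was weighed as well. The 3056 nuclear genes between the lowest and highest average expression of the 13 had a median of -0.001, so that range as a whole did not fall. Of these nuclear genes, 265 lay at or below the mitochondrial median. The range is wide, and the median of all tested genes was 0.011 after TMM scaling. This test therefore cannot exclude a fall confined to the most abundant transcripts. The mitochondrial ribosomal RNAs did not pass the test, with log2 fold changes of -0.19 for MT-RNR2 (SE 0.07, adjusted p = 0.072) and -0.01 for MT-RNR1 (SE 0.09, adjusted p = 0.96), genes chosen after their values were seen. The hypothesis that MGA lowers mitochondrial messenger RNA may be kept, but the list's call ends with an estimated correlation (adjusted p = 0.15), and poly(A) selection, which reads these RNAs through their tails, was not tested.

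Among the 39 genes with the largest fitted changes besides MGA were 10 gene models with a near-identical copy or a read-through partner, the GOLGA6L9 pair counted here once (9), and reads divided between near-identical gene models would shrink once summed. The partners were listed by hand after a first automatic match by symbol had been run and discarded, since it gave AGAP9 and EVI5L wrong partners. Summed, 6 of the 9 had a log2 fold change under 1 in size, which just meets the bound of 2 in 3 set for this explanation (7 of 10 with both GOLGA6L9 models counted, as the discarded match did), as for GOLGA6L9 (-7.04 alone, 0.36 summed) and DYX1C1-CCPG1 (6.63 alone, 0.68 summed). Divided reads may account for the size of these 6 changes, but this test cannot decide it. A real change of a weak model would also shrink when summed with a more abundant partner. The GOLGA6L9 models moved in opposite directions with MGA (log2 fold changes -7.04 and 3.79). Summed, 3 of the 6 passed the edgeR test, 1 of them in the other direction. For P2RX5 (-1.42), TRIM34 (1.57) and HIST2H2AA3 (1.24) a change of over 1 stayed, so division of reads is at most part of it.

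The MYC target list was lower with MGA, and the explanations weighed were its cell-cycle members, abundance and gene length. Without MCM4, MCM5, PLK1, PLK4, UNG and CDK4, the 49 other members kept a median of -0.15 (camera p = 4.2e-05), a call that ended with an estimated correlation (p = 0.056). The list's median lay at percentile 0.02 (on a scale of 0 to 100) of 10000 random lists matched on average expression and at percentile 0.3 of those matched on gene length, which argues against abundance or length as the whole cause. That MGA lowers MYC targets beyond their cell-cycle members stays a hypothesis, since slower growth could also lower them and no measure of growth was used here.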
